A study of Mus musculus with 6 samples.

How the data were processed

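RNA was measured in AB22 cells, a murine malignant mesothelioma line, carrying a lentiviral vector in which doxycycline switches on a short hairpin RNA. Per the labels' protocols, cells were infected with virus for a control hairpin (shCTRL) or a hairpin against Hmgb1 (shHMGB1) at a multiplicity of infection of 20, selected with puromycin at 4 µg/mL, kept in 5% oxygen and used 7 to 10 days after doxycycline was added at 1 µM. Total RNA came from cells synchronized in G1, ribosomal RNA was subtracted with RiboMinus, and libraries were made with a TruSeq RNA kit. The series lists 3 biological replicates of each group, with the letters A, B and C in both groups, so 6 libraries entered the comparison. Whether each replicate was a separate infection is not given in the sources used here, so p-values measure the spread between these cultures. The accessibility and break-mapping experiments that the series text mentions were not analysed here.

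Per the submitters' processing notes, the authors used Trimmomatic 0.32, STAR 2.5.3a, featureCounts and edgeR with the builds mm10 and GRCm38. The deposited table holds 1 value per gene and library for 12134 gene symbols, and all 6 of its columns were matched to samples by name. The deposited values are log2 RPKM (read counts scaled by gene length and library size, on a log2 scale), from -9.20 to 17.74, although linear RPKM had been assumed when the tests were fixed. They were therefore raised as powers of 2 before use. Base 2 was checked from the sum of RPKM times annotated exonic length in kilobases, which came to 1330000 to 1570000 per library with base 2 and 15400000 to 66400000 with base e. Strandedness of the counting, the gene model and the gene filter are not given in the sources used here.

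The depth of each library was recovered from the steps between low values. Library sizes were searched with 1610 genes that have a single transcript in GENCODE M21 (GRCm38). At the sizes found, 90.4% of the values of those genes lay within 0.05 of a whole read after a prior of 0.25 reads, scaled by library size, was taken off. A whole-number gene length between 40 and 60000 bases that made all 6 values whole within 0.02 reads was found for 12133 of the 12134 genes. With wrong library sizes it was found for 0 of 500 genes (0.0%). On simulated reads the library sizes were recovered with an error of 0.0% and the reads of all 200 simulated genes, 100.0%, were returned. The reads add up to 13855210, 12867646 and 23426483 in shCTRL replicates A, B and C and to 18812663, 20366814 and 15093543 in shHMGB1 replicates A, B and C, over the listed genes. The library sizes behind the deposited values differ from those totals by factors of 0.845 to 1.09, so a scaling between libraries is already in the values. One read on a gene of 2 kb corresponds to 0.0196 to 0.0460 RPKM.

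Genes with a mean of at least 0.5 RPKM over the 6 libraries were tested, 11669 in all, which left out 465. The test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.1), with group as the only term and eBayes with trend and robust set, two-sided, with Benjamini-Hochberg adjustment at 0.05. Fold changes are shHMGB1 over shCTRL on this scale, which understates the change of genes with low values. Errors of log2 fold changes are limma's standard errors and intervals cover 95%. With 3 libraries against 3, an exact permutation test of a single value cannot give a p under 0.1, so p-values here come from the model over all genes. No 2 libraries held identical values for more than 2 genes, so no column was a copy of another. This cannot show whether 2 libraries came from the same culture. All 6 were counted as separate samples because the series lists them as biological replicates.

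Before the data were examined, 26 gene lists and a rule for the genes to name were fixed, together with the tests and most alternatives. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation and with fry. Each list had at least 3 tested members. The rule names Hmgb1 first and up to 12 genes in each direction past the threshold with non-overlapping groups. With fewer than 10 genes past the threshold, as here, it names the 10 genes with the smallest p in each direction. It also takes from each list the members past the threshold or, where none passes, the 2 tested members with the highest mean RPKM, and Hmgb2 and Hmgb3 in any case. Genes outside the rule are marked as chosen after their values were seen. The values of 1 further gene are not reported here.

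The alternatives fixed beforehand were a pseudocount of 1 or 0.01, no filter, a mean of at least 5 RPKM, 3 other scalings between libraries, eBayes without trend and robust, array quality weights, the replicate letter as a block, leaving out each library in turn, a minimum log2 fold change of 1, and the other list tests. Added after the data were seen were the deposited log2 values with nothing added, a regression of each library's deviations on splines of GC content and transcript length (5 degrees of freedom each, over the 11423 tested genes with an annotated transcript), limma's voom on the recovered reads with and without sample quality weights, and the 18S ribosomal RNA level as a covariate. Read recovery and drawing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

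The limma test was tested on simulated reads in 10 simulations, drawn from the recovered means, spread and library sizes, each with 200 genes changed by 1.5- to 8-fold. A list of 30 further genes was shifted by 1.5-fold, and most other genes of chromosome 12 by -0.2 in log2. The test called 3.01% of 498 genes changed by 1.5-fold and 29.1% of 494 changed by 2-fold. It called 75.1% of 493 changed by 4-fold, 92.2% of 486 changed by 8-fold and 0.03% of 110763 unchanged ones. The adjusted threshold loosens as more genes are called, and only 3 were called in the real data. These shares may therefore be too high for this comparison. In the same simulations camera called 10 of 10 lists of 30 genes shifted by 1.5-fold and 0 of 250 unchanged lists. The simulated genes varied independently, so list calls among correlated genes were not tested by this. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.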

Results

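Gene expression was compared between AB22 mesothelioma cells expressing a hairpin against Hmgb1 and cells expressing a control hairpin, with 3 RNA-seq libraries in each group. HMGB1 is an abundant chromatin protein that binds and bends DNA, and the series asks how nucleosomes bear on DNA breaks made by irradiation. The comparison asks which transcripts differ in unirradiated G1 cells when Hmgb1 is silenced. Depth was 12867646 to 23426483 reads per library over the listed genes. Values are RPKM, as mean ± SD over 3 libraries unless stated, and locations are those of GENCODE M21 on GRCm38.

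Hmgb1 itself fell from 36.9 ± 7.43 RPKM in shCTRL to 5.59 ± 1.70 RPKM in shHMGB1 (SD, n = 3 each), so that 15.1% of the control level was left. Its reads numbered 1842, 1991 and 3289 in shCTRL replicates A, B and C and 565, 515 and 228 in shHMGB1 replicates A, B and C. The log2 fold change was -2.73 ± 0.26 (SE; 95% interval -3.33 to -2.13; adjusted p = 0.0269), and all 3 shHMGB1 libraries lay below all 3 shCTRL libraries. The gene lies on the minus strand of chromosome 5 from 149046702 to 149184489. Its annotated exons share 42 bases with Uspl1 on the other strand and 37 bases with Mm2pr, and 10 pseudogenes of Hmgb1 are annotated, so some of its reads may be shared with them. The adjusted p rose to 0.0546 when only genes of at least 5 RPKM were tested, and to 0.137, 0.248, 0.115 and 0.197 without shCTRL replicate A, B or C or shHMGB1 replicate B, with log2 fold changes of -2.79, -2.57, -2.83 and -2.78. Hmgb2 and Hmgb3, which encode related HMG-box proteins, did not pass the test. Hmgb2 measured 3.69 ± 0.79 RPKM in shCTRL and 4.62 ± 2.26 RPKM in shHMGB1 (adjusted p = 0.822), and Hmgb3 measured 4.05 ± 0.51 RPKM and 3.74 ± 1.61 RPKM (adjusted p = 0.840).

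Besides Hmgb1, 2 genes passed the threshold, and both fell. Aldh3a1, an aldehyde dehydrogenase on chromosome 11 (61207537 to 61218421), fell from 5.48 ± 1.55 RPKM to 0.399 ± 0.069 RPKM, a log2 fold change of -3.45 ± 0.27 (SE; adjusted p = 0.0171). Gm11867, a predicted non-coding transcript on chromosome 4 (18407349 to 18891842), had 37, 64 and 196 reads in shCTRL replicates A, B and C and 0 reads in each of the 3 shHMGB1 libraries (adjusted p = 0.0171). With the reads of each group pooled and a floor of 3 reads over the whole shHMGB1 group, it was at least 112-fold lower. That bound is not one for each culture, since shCTRL replicate C gave 196 of the 297 pooled reads. The floor corresponds to 0.0278 RPKM, and shCTRL replicates A, B and C measured 1.42, 3.09 and 4.02 RPKM. In all, 3 of 11669 tested genes changed, 0 higher and 3 lower. The unadjusted p was under 0.05 for 923 genes, where chance alone gives 583 on average. Genes vary together, so such a count can stray from 583 without a group difference. Of the 923 genes, 441 were higher and 482 were lower in shHMGB1. On the recovered reads limma's voom called the same 3 genes, with 940 at an unadjusted p under 0.05. The count went to 0 without shCTRL replicate B, without shCTRL replicate C or without shHMGB1 replicate B, and to 8 without shHMGB1 replicate A. Leaving out shCTRL replicate A ended the call of Hmgb1 and kept the other 2. With a pseudocount of 1 the adjusted p of Gm11867 was 0.144, and both genes fall outside the filter of 5 RPKM.

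The next genes by p in each direction did not pass the threshold, although their groups did not overlap. Those with lower values in shHMGB1 included Spon2, a secreted matrix protein, with 16.8 ± 1.49 RPKM in shCTRL and 3.31 ± 1.30 RPKM in shHMGB1 (log2 fold change -2.37 ± 0.26 SE, adjusted p = 0.061). Stra6, the membrane receptor for retinol-binding protein, measured 3.70 ± 1.13 RPKM and 0.529 ± 0.120 RPKM, and Gbp2b, an interferon-inducible GTPase, measured 11.7 ± 2.84 RPKM and 2.57 ± 0.59 RPKM (adjusted p = 0.061 for both). Macc1, a gene on chromosome 12 (119314270 to 119469987), had 31, 54 and 240 reads in the shCTRL libraries and 2, 0 and 1 in the shHMGB1 libraries, 325 against 3 in all. Scaled by the library sizes of the 2 groups, that is a ratio of 122 with an exact 95% counting interval of 41.4 to 596. The adjusted p in limma was 0.1. The chemokine Ccl8 had a log2 fold change of -1.83 (adjusted p = 0.1), and the non-coding E330013P04Rik and the interleukin-33 receptor gene Il1rl1 had -1.30 and -1.46 (adjusted p = 0.214 for both). Il1rl1 was the most abundant of these, with 286.6 ± 7.97 RPKM in shCTRL and 107 ± 31.9 RPKM in shHMGB1. Of the alternatives that tested each gene, Spon2 passed in 5 of 21, Stra6 in 4 of 20, Gbp2b in 4 of 21 and Il1rl1 in 3 of 21, and Macc1, Ccl8 and E330013P04Rik passed in 2 each.

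The 10 genes with the smallest p among those with higher values in shHMGB1 had adjusted p-values from 0.061 to 0.249. Klhl22, which encodes a substrate adaptor of a cullin-3 ubiquitin ligase, stood first with 0.512 ± 0.104 RPKM in shCTRL and 2.61 ± 0.47 RPKM in shHMGB1 (log2 fold change 2.15 ± 0.25 SE, adjusted p = 0.061). The collagen genes Col5a3 and Col4a1 had log2 fold changes of 1.13 ± 0.14 and 1.28 ± 0.21 (SE), from 14.2 ± 0.93 to 31.2 ± 2.38 RPKM and from 21.0 ± 5.61 to 50.1 ± 4.32 RPKM (adjusted p = 0.0784 and 0.234). The basement membrane protein gene Nid2, the collagen receptor gene Itga1 and the proteoglycan gene Lum had log2 fold changes of 1.06, 1.22 and 2.35 (adjusted p = 0.24, 0.24 and 0.168). The adhesion molecule gene Mcam measured 2.28 ± 0.88 RPKM and 11.8 ± 3.25 RPKM (log2 fold change 2.36, adjusted p = 0.14). Tmem2, a hyaluronan-degrading membrane protein gene, the transporter gene Slc16a6 and the cytokine gene Il34, a ligand of the CSF1 receptor, had log2 fold changes of 0.99, 1.09 and 1.11. Klhl22 passed in 7 of the 20 alternatives that tested it and Mcam in 5 of 21, the other 8 passed in 1 or 2 each, and none of the 10 changed sign in any.

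**Figure D1:**
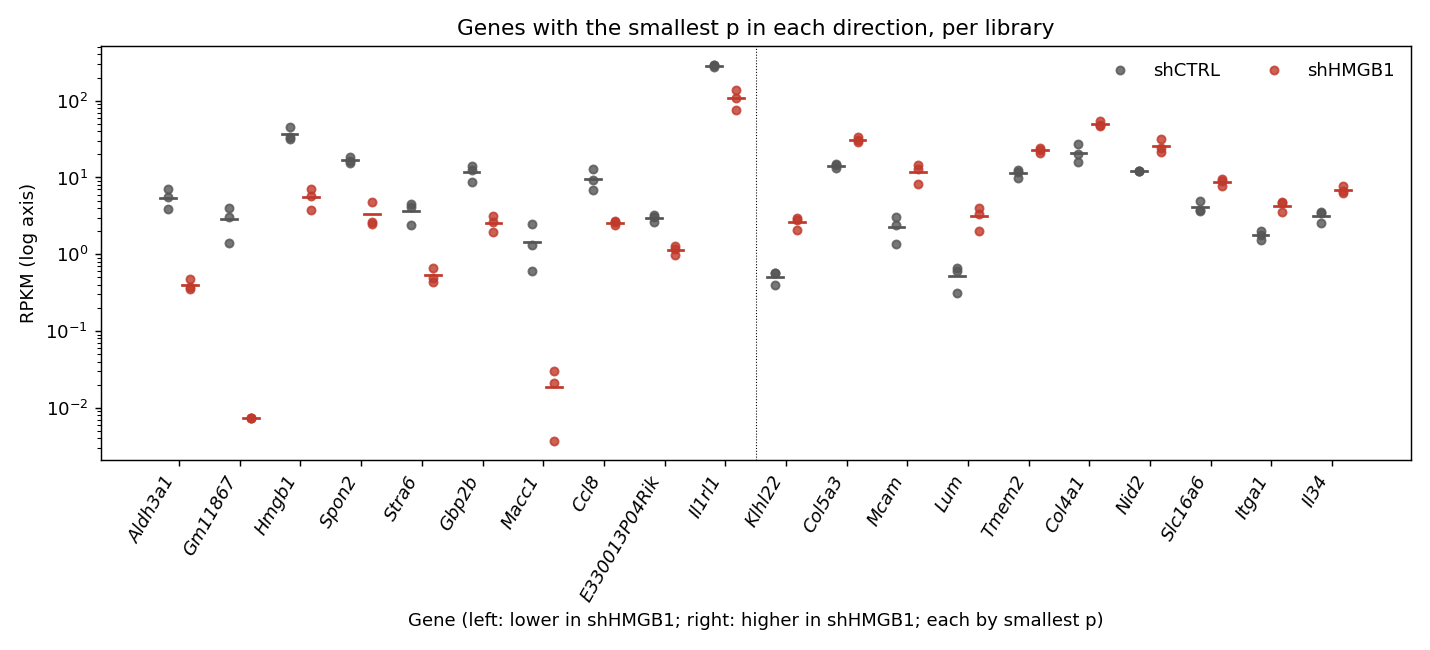
RPKM on a log axis for the 10 genes with the smallest p in each direction, lower in shHMGB1 on the left and higher on the right, with 1 point per library (grey shCTRL, red shHMGB1) and a bar at the mean of 3. Hmgb1 lies between 3.80 and 7.18 RPKM in shHMGB1, below every shCTRL library, and the 3 points of Gm11867 in shHMGB1 stand for 0 reads and sit at the offset held in the deposited values.

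Of the 26 gene lists, 8 were called by camera at the preset correlation, 5 toward higher and 3 toward lower values in shHMGB1. With an estimated correlation 0 of the 26 were called, and fry called 2 of them, p53 targets and interferon response (adjusted p = 0.0133 for both). The estimated correlation was 0.853 for G2/M and mitosis, 0.775 for ribosomal proteins and 0.122 to 0.258 for the matrix, G1/S and cholesterol lists. It was 0.014 for interferon response, -0.023 for p53 targets and 0.047 for mesothelial markers, close to the preset 0.01. For these last lists a high correlation among members does not account for the lost call, and the reason was not tested. The 3 genes past the threshold over all genes belong to none of the lists, so 0 members of any list passed there. Rescaling the libraries to equal sums moved the median of all genes from 0.01 to 0.36 and raised the medians of the lists with it, and camera kept all 8 calls.

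The interferon response list had 16 of 23 tested members lower and 7 higher, with a median log2 fold change of -0.33 and adjusted p = 0.000251. With an estimated correlation, which came to 0.014, the adjusted p = 0.331. Its 3 shHMGB1 libraries had mean deviations of -0.18, -0.18 and -0.11, all below the 3 shCTRL libraries at 0.10, 0.20 and 0.17. Adjusted over the list alone, 2 members passed, Gbp2 at 34.6 ± 3.52 RPKM in shCTRL and 16.9 ± 3.98 RPKM in shHMGB1, and Zbp1 at 1.74 ± 0.63 RPKM and 0.466 ± 0.086 RPKM, both chosen after their values were seen. Its most abundant members, Psmb8 and Ifi27, had log2 fold changes of -0.18 and -0.45. The camera call was absent among genes of at least 5 RPKM (adjusted p = 0.232), and the median was -0.21 without shCTRL replicate B. Under rescaling to equal sums it was 0.03, below the 0.36 of all genes. The p53 target list was called toward higher values, with 21 of 30 members positive, a median of 0.17 and adjusted p = 0.0238, or adjusted p = 0.331 with an estimated correlation. Of its members 0 passed adjusted over the list alone, and its most abundant, Ccng1 and Ephx1, had log2 fold changes of 0.02 and -0.29. The call was absent without shCTRL replicate A (adjusted p = 0.0726) and without shHMGB1 replicate A (adjusted p = 0.137, median 0.11).

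Both cell cycle lists were called toward higher values. The list for G2/M and mitosis had 27 of 28 members positive, with a median log2 fold change of 0.89 and adjusted p = 6.88e-09, or adjusted p = 0.713 with an estimated correlation. Its mean deviations were -0.61, 0.03 and -0.58 in the shCTRL libraries and -0.10, 1.23 and 0.04 in the shHMGB1 libraries A, B and C. Its median was 0.43 without shHMGB1 replicate B, 0.51 with a pseudocount of 1, 1.46 with array quality weights and 1.80 in voom with sample quality weights. Among genes of at least 5 RPKM it was 0.37 and the call was absent (adjusted p = 0.232). Anln, which encodes anillin, measured 13.1 ± 1.85 RPKM in shCTRL and 14.7 ± 3.65 RPKM in shHMGB1, and the topoisomerase gene Top2a measured 6.09 ± 0.72 RPKM and 8.32 ± 3.51 RPKM. The list for G1/S and DNA replication had 28 of 34 members positive, a median of 0.34 and adjusted p = 3.14e-05, or adjusted p = 0.713 with an estimated correlation. Its mean deviations were -0.22, -0.14 and -0.21 in the shCTRL libraries and 0.06, 0.45 and 0.06 in the shHMGB1 libraries A, B and C. Its median was 0.16 without shHMGB1 replicate B, 0.19 with a pseudocount of 1, 0.14 among genes of at least 5 RPKM and 0.57 in voom with sample quality weights. Camera at the preset correlation kept the call in all 21 alternatives. Its adjusted p was 0.00303 without shHMGB1 replicate B and 0.0229 among genes of at least 5 RPKM. Pcna and Dut, the list's most abundant members, had log2 fold changes of -0.05 and -0.28. Adjusted over the list alone, 0 members of either list passed.

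The list of mesenchymal and extracellular matrix genes had 33 of 44 members positive, a median of 0.27 and adjusted p = 0.00152, or adjusted p = 0.713 with an estimated correlation. Adjusted over the list alone, 4 members passed, Lum and Col4a1 from above and, chosen after their values were seen, Col4a2 at 8.73 ± 2.31 and 24.8 ± 7.55 RPKM and Dcn, the proteoglycan decorin, at 3.71 ± 1.35 and 9.90 ± 2.53 RPKM in shCTRL and shHMGB1. The abundant cytoskeletal members Acta2 and Vim had log2 fold changes of 0.11 and 0.01. The median was 0.17 without shCTRL replicate B or without shHMGB1 replicate C, 0.43 without shHMGB1 replicate A, 0.15 with GC content and transcript length regressed out, and -0.04 with the 18S level as a covariate, where the call was absent (adjusted p = 0.485). Of 20 mesothelial markers only 6 were tested. Those 6 were called toward lower values, with 5 negative, a median of -0.40 and adjusted p = 0.00299, or adjusted p = 0.331 with an estimated correlation. Adjusted over the list alone, 3 passed. They were mesothelin, Msln, at 67.2 ± 13.6 RPKM in shCTRL and 32.9 ± 5.66 RPKM in shHMGB1 and, chosen after their values were seen, Bnc1 and Gas1 with log2 fold changes of -0.69 and -0.64. Efemp1, the most abundant, had -0.16, and the median among markers of at least 5 RPKM was -0.17 (adjusted p = 0.0294). Cholesterol biosynthesis genes were called toward higher values, with 20 of 24 positive, a median of 0.40 and adjusted p = 0.000342, or adjusted p = 0.713 with an estimated correlation. Msmo1 and Sqle had log2 fold changes of 0.44 and 0.24. The cholesterol call was absent without shHMGB1 replicate A (adjusted p = 0.104), and the median was 0.24 without shCTRL replicate C.

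Cytoplasmic ribosomal protein genes were called toward lower values, with 73 of 80 negative, a median of -0.22 and adjusted p = 3.14e-05, or adjusted p = 0.906 with an estimated correlation. Of them 0 had an unadjusted p under 0.05 in limma and 0 passed adjusted over the list alone, and Rplp1 and Rps27, the most abundant, had log2 fold changes of -0.08 and -0.26. The mean deviation was -0.48 in shHMGB1 replicate C and between -0.09 and 0.27 in the other 5 libraries. Without that library the median was -0.02 (adjusted p = 0.696). It was -0.13 without shCTRL replicate B, -0.43 without shHMGB1 replicate A and -0.11 with GC content and transcript length regressed out. Under rescaling to equal sums it was 0.13, below the 0.36 of all genes, and the call toward lower values was kept. The direction turned with the 18S level as a covariate (median 0.09, adjusted p = 0.0477), and the call was absent after quantile normalization (median -0.05, adjusted p = 0.551).

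Lists bearing on chromatin were not called in the test over all 6 libraries, and 3 of them were in alternatives to it. The 45 tested replication-dependent histone genes had a median of 0.00 with 23 positive and 22 negative (adjusted p = 0.932), and mean deviations that spread from -0.60 in shHMGB1 replicate C to 0.83 in shHMGB1 replicate B. Hist1h4d, one of its most abundant members, measured 88.2 ± 28.0 RPKM in shCTRL and 85.1 ± 35.0 RPKM in shHMGB1, and Hist1h2bc had a log2 fold change of 0.05. Camera called the histone list lower without shHMGB1 replicate B (median -0.33), and higher without shCTRL replicate B (0.24), without shHMGB1 replicate C (0.27), with array quality weights (0.45), in voom with sample quality weights (0.62) and with the 18S covariate (0.39). These near-identical genes can share reads, so single members are uncertain. Replacement histone variants had a median of -0.03 over 10 genes (adjusted p = 0.825), with 0.14 for H3f3b and -0.41 for H3f3a, whose exons overlap an antisense gene. Medians were 0.05 for 12 other HMG genes, with 0.00 for Hmgn1 and -0.18 for Ubtf, and 0.05 for 26 histone chaperones, with -0.36 for Npm1 and 0.08 for Rbbp7 (adjusted p = 0.792 for both lists). The other HMG genes were called higher in voom with sample quality weights (median 0.27, adjusted p = 0.0478). Chromatin remodellers had a median of 0.19 over 32 genes (adjusted p = 0.255), with -0.26 for Ruvbl1 and -0.10 for Ruvbl2, and were called higher without shHMGB1 replicate A (median 0.42, adjusted p = 0.0128).

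The DNA repair lists were not called in that test either. Non-homologous end joining genes had a median of -0.07 over 15 genes (adjusted p = 0.807), and Xrcc5 and Xrcc6, which encode the Ku subunits, had log2 fold changes of -0.43 ± 0.18 and -0.27 ± 0.19 (SE). Homologous recombination genes had a median of 0.06 over 16 genes (adjusted p = 0.348), with 0.07 for Nbn and 0.06 for Mus81, and were called higher without shCTRL replicate B (median 0.16, adjusted p = 0.029) and with the 18S covariate (median 0.18, adjusted p = 0.0362). DNA damage signalling genes had a median of 0.06 over 16 genes (adjusted p = 0.792), with 0.05 for Parp1 and -0.29 for Rad17. Adjusted over the list alone, 0 genes of the chromatin and repair lists passed.

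Among the lists for signalling and stress, inflammatory and NF-kB targets had a median of 0.17 over 20 genes (adjusted p = 0.102), and 1 passed adjusted over the list alone, Csf1, the macrophage growth factor gene, at 109 ± 12.7 RPKM in shCTRL and 205 ± 28.7 RPKM in shHMGB1. Ccl7 had a log2 fold change of 0.72. Camera called this list higher without shCTRL replicate A (median 0.17), without shCTRL replicate B (0.16), without shHMGB1 replicate C (0.20), with GC content and transcript length regressed out (0.10) and with the 18S covariate (0.32). HMGB1 receptors and partners had a median of -0.08 over 6 genes (adjusted p = 0.636), with 0.36 for Thbd and -0.20 for Sdc1. The integrated stress response had a median of 0.01 over 23 genes (adjusted p = 0.807), with -0.20 for Atf4 and -0.46 for Psat1. Autophagy and lysosome genes had a median of -0.03 over 31 genes (adjusted p = 0.156), with 0.10 for Lamp1 and -0.34 for Gabarap, and were called lower without shCTRL replicate A (median -0.10, adjusted p = 0.0136) and with the 18S covariate (median -0.11, adjusted p = 0.0477). NRF2 antioxidant genes had 0.03 over 22 (adjusted p = 0.792), with 0.13 for Ftl1 and 0.49 for Fth1, and hypoxia and glycolysis genes had 0.02 over 33 (adjusted p = 0.792), with -0.20 for Ldha and -0.26 for Pkm. Mitochondrially encoded genes had -0.10 over 8 (adjusted p = 0.636), with -0.37 for mt-Co1 and 0.04 for mt-Cytb. In 5 of the 26 lists, all uncalled, the median, the mean and the direction of the test differed in sign.

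Markers of other cell types were scarce. Of 20 macrophage and leukocyte markers 3 were tested, with a median of 0.10 (adjusted p = 0.879). Ncam1 measured 8.66 ± 1.29 RPKM in shCTRL and Cd14 7.00 ± 0.84 RPKM. Of 12 endothelial markers 3 were tested, with a median of -0.16 (adjusted p = 0.825), and Flt1 and, chosen after its values were seen, Eng passed adjusted over the list alone in opposite directions, with log2 fold changes of 0.85 and -0.90, while Kdr had -0.16. Non-polyadenylated and nuclear RNAs, which follow how the RNA was selected and depleted, had a median of -0.25 over 11 genes (adjusted p = 0.0774), with -0.46 for Rn7sk and 0.11 for Rmrp. They were called lower without shCTRL replicate C (median -0.51), without shHMGB1 replicate A (-0.57) and with the replicate letter as a block (-0.25). The same call came with array quality weights (-0.49), in voom with sample quality weights (-0.55) and under rescaling to equal sums (0.10 against 0.36 for all genes). Their mean deviations were 0.46, 0.53 and -0.25 in shCTRL replicates A, B and C and 0.25, -0.50 and -0.49 in shHMGB1 replicates A, B and C. The 18S ribosomal RNA left in the libraries was 14.5, 15.9 and 11.1 log2 RPKM in shCTRL and 13.1, 11.3 and 9.28 log2 RPKM in shHMGB1 replicates A, B and C. The library with the most 18S, shCTRL replicate B, had mean deviations of -0.33 for the matrix list and 0.23 for ribosomal proteins, and the library with the least, shHMGB1 replicate C, had 0.41 and -0.48.

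**Figure D2:**
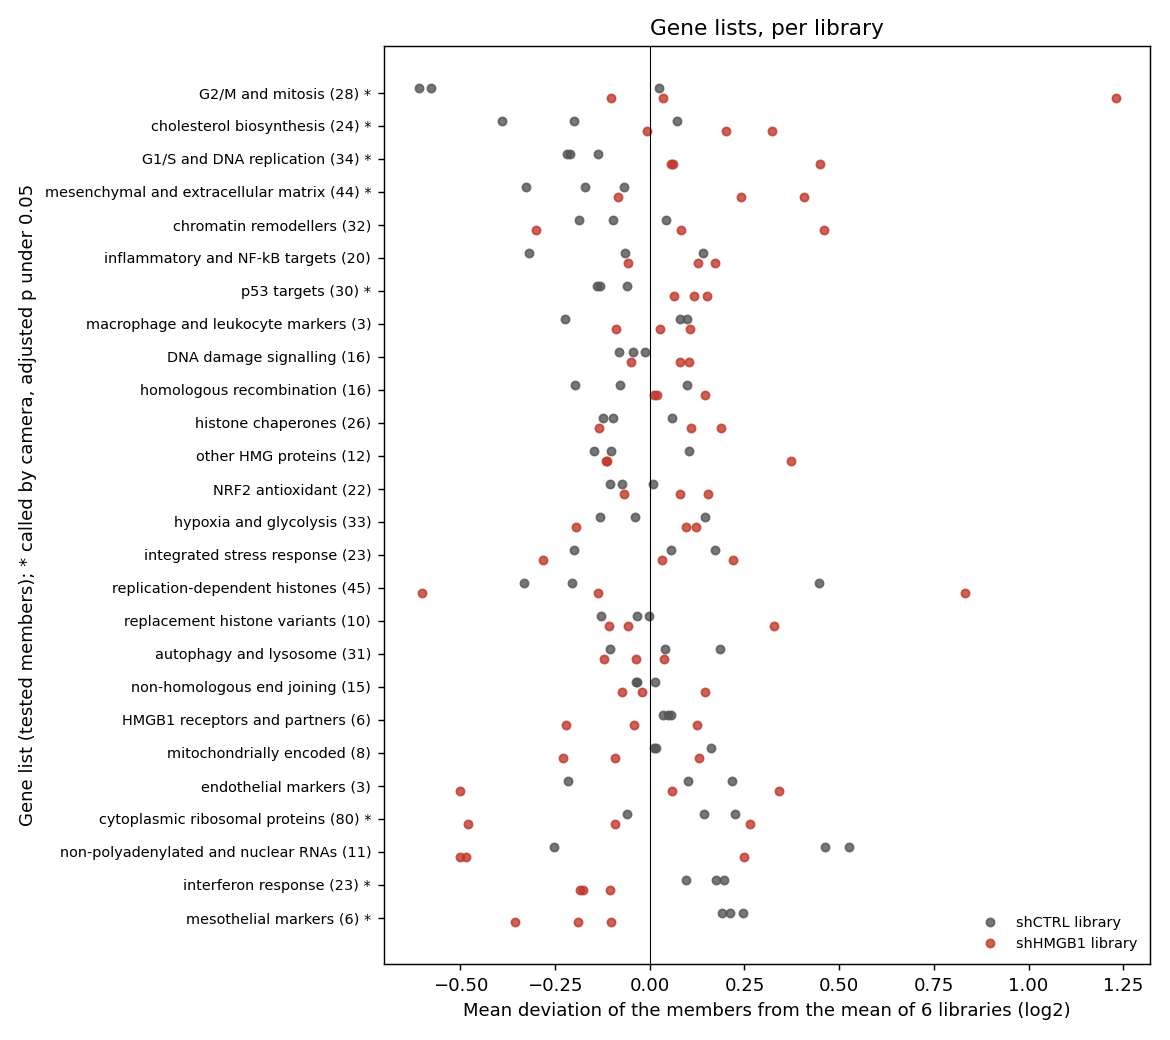
Mean deviation of the members of each of the 26 lists from the mean of the 6 libraries (log2), with 1 point per library, grey for shCTRL and red for shHMGB1, and the number of tested members in parentheses. Lists with an asterisk were called by camera at the preset correlation. The 2 groups do not overlap for interferon response, mesothelial markers, p53 targets and G1/S and DNA replication, while shHMGB1 replicate B alone reaches 1.23 for G2/M and mitosis.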

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

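The alternatives with GC content and transcript length, the bare log2 values, voom and the 18S covariate were chosen after seeing the data. The log2 fold change of Hmgb1 stayed negative in all 21 alternatives, from -2.93 to -2.36, with adjusted p-values from 0.000578 to 0.248, and passed in 16. It was -2.73 but not past the threshold (adjusted p = 0.0546) with a minimum of 5 RPKM. Without single libraries it ranged from -2.93 to -2.48, and the count of changed genes ranged from 0 to 8, all of them lower. The 3 changed genes became 0 with a minimum of 5 RPKM, which leaves out 2 of them. They became 5 (2 higher) with libraries rescaled to equal sums, which raised the median of all genes by 0.35, and 5 (2 higher) with the 18S covariate. Without trend and robust moderation 1 higher gene, Klhl22, was added. Array quality weights gave 21 (7 higher, 14 lower), the GC and length regression 7 (1 higher, 6 lower), and voom with sample quality weights 362 (161 higher, 201 lower). The array weights were 1.858, 1.086 and 0.902 in shCTRL and 0.475, 2.336 and 0.495 in shHMGB1 replicates A, B and C. The shHMGB1 side of that fit thus leans on replicate B, which stood highest for G2/M and mitosis (mean deviation 1.23) and replication-dependent histones (0.83). The weights in voom are not given here. The cause of the higher counts was not tested. Plain voom, the bare log2 values and the 2 other scalings gave 3 each and kept the same 3 genes.

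Whether the letters A, B and C pair the libraries is not given by the labels and is not settled by the values. Deviations of same-letter libraries correlated at 0.15, -0.10 and 0.48, and 3 libraries correlated best with their own letter. The libraries were therefore not taken as pairs in the main test. With the letter as a block limma called 7 genes, 2 higher and 5 lower, and the adjusted p of Hmgb1 was 0.00742. It gave 1254 genes an unadjusted p under 0.05, in place of 923. Camera then called 9 lists, the added one being non-polyadenylated and nuclear RNAs (adjusted p = 0.0126).

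Camera called 8 lists, and 6 to 11 in the alternatives with the preset correlation. It called 0 with an estimated correlation, fry 2 by its directional p and 0 by its mixed p. The replication-dependent histones, not called at first, were called toward higher values with array weights (median 0.452), voom with sample weights (0.616), the 18S covariate (0.390) and without shCTRL replicate B (0.236) or shHMGB1 replicate C (0.268), and toward lower values without shHMGB1 replicate B (-0.326). Ribosomal proteins turned to a median of 0.094 with the 18S covariate. The cause was not tested. Of 1519 values compared for the genes the rule names other than Hmgb1, 1462 kept their side of the threshold, 7 fell from past it to short of it, 50 came to pass it and 0 reversed past it, while 85 small changes differed in sign. Only Aldh3a1 and Gm11867 were past it in the main test, so only they could fall short. Aldh3a1 passed in 17 of the 20 alternatives that tested it and Gm11867 in 16 of 20. Most of the 1462 are values that passed in neither setting, so they do not measure how stable the calls are. Depth limits genes with few reads. Simulated 2-fold changes were called in 29.1% of 494 genes, in simulations with more changed genes than were called here.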

Other observations

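The tests of chromosome dosage, of single libraries and of the axis across libraries were chosen after the results they bear on were seen, as were the genes and groups named here.

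Expression on chromosome 12 was lower in shHMGB1. Its 388 tested genes had a median log2 fold change of -0.17 ± 0.02 (bootstrap SE over genes, not over cultures), with 267 of them negative. The medians of the other autosomes and X lay between -0.07 and 0.09. The median deviations of chromosome 12 were 0.01, 0.12 and 0.13 in the 3 shCTRL libraries and -0.09 in each of the 3 shHMGB1 libraries. Among genes with at least 20 reads in every library of one group and at most 2 in every library of the other, 2 were found, Gm11867 on chromosome 4 and Macc1 on distal chromosome 12, both present in shCTRL. None of the other 9 splits of the 6 libraries gave such a gene. By annotation, protein coding genes had a median of 0.02 over 10454 genes and TEC genes, whose transcripts are still to be experimentally checked, had 0.17 over 130. The other 7 classes with at least 20 genes had medians below 0, of -0.26 for 98 snoRNAs, -0.18 for 24 transcribed unprocessed pseudogenes, -0.14 for 207 processed pseudogenes, -0.09 for 156 lincRNAs, -0.08 for 114 antisense genes, -0.07 for 100 processed transcripts and -0.06 for 23 bidirectional promoter lncRNAs.

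The chromosome 12 shift is not accounted for by GC content and transcript length, since it was -0.193 after both were regressed out, against -0.05 for the lowest other chromosome. A lower dose of the whole chromosome in the shHMGB1 cells is a candidate explanation. All 19 windows of 20 genes along it, a share of 1, had a median below 0, from -0.34 to -0.00. With 68.8% of its genes negative, most windows would fall below 0 under any shift spread along the chromosome. The windows therefore show that the shift was spread along it and cannot single out dosage. They end at position 113189523, short of Macc1. Among the 10 splits of the libraries 1, the real one, gave a shift as large (0.183 against at most 0.11 in the others), but 10 splits are too few for a share under 0.05. Chromosome 12 also ranked first among chromosomes in several other splits. The shift of 0.11 came with shCTRL replicate A and shHMGB1 replicates A and B set against the rest. An effect of Hmgb1 silencing itself on this chromosome stays open and was not tested, and no DNA measurement was used here.

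For the higher cell cycle lists in shHMGB1, 1 library with more cycling cells and a difference between the groups cannot be told apart. The values weighed here are those of the G2/M and mitosis list only. Without shHMGB1 replicate B the median of the G2/M and mitosis list was 0.425 in place of 0.89 and camera at the preset correlation still called it (adjusted p = 1.76e-05), but that library was left out because it stood highest, at a mean deviation of 1.23, so a fall decides nothing. Without shCTRL replicate B, the highest control library, the median was 1.146. GC content and transcript length bias is argued against, since the median was 0.898 after that correction. The remaining difference, in cells described as synchronized in G1, stays open, and so does an effect of the silencing.

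The libraries spread along an axis that crosses the 2 groups. The first principal component held 56.3% of the variance and ran from -33.5 in shCTRL replicate B to 53.5 in shHMGB1 replicate C, with shHMGB1 replicate A at -25.3. GC content and transcript length explained 6.5% to 26.7% of each library's deviations. Those deviations correlated with log2 transcript length at r = -0.229, -0.305 and 0.088 in shCTRL replicates A, B and C. In shHMGB1 replicates A, B and C they correlated at -0.303, 0.104 and 0.432, and the 6 libraries rank alike by this r and by the first component. After both were regressed out the first component held 48.8%, but of the smaller variance that was left. How much of the axis they account for is therefore not settled. Computed without ribosomal RNA genes, the component followed the 18S level over the 6 libraries (r = -0.909, exact permutation p = 0.0167, or 0.0334 adjusted over the 2 relations computed, rho = -0.886, exact permutation p = 0.0333), and r was -0.764 without the 2 libraries farthest from the median 18S level. A difference in library preparation that also sets the residual ribosomal RNA is therefore a candidate explanation. A biological difference between the cultures and a bias with transcript length stay open.

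For the count of changed genes, 1 of the 10 splits of the libraries, the real one, gave 3 genes, and the highest of the others gave 1. For lists, 5 of the 10 splits gave at least the 8 that the real split gave, and the highest of the others gave 9. A design with 10 splits cannot give a share under 0.05. The groups of 1630 genes, 14.0% of those tested, did not overlap. The average over all 10 splits is 10% by arithmetic, and the share in other splits was not computed. An excess over chance is therefore not shown by this.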
